A study of Mus musculus with 4 samples.

How the data were processed

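Gene expression was measured by one-colour (Cy3) microarrays in 4 samples of mouse embryonic fibroblasts, 1 per condition. Per the labels, fibroblasts transduced with Oct3/4, Sox2, Klf4 and c-Myc were grown for 72 hours at 21% or 5% O2, and untransduced fibroblasts for 10 days at 21% or 5% O2. Total RNA was isolated with Trizol and labelled by the Quick Amp protocol version 5.7, per the labels' protocols.

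Signals were extracted with Agilent Feature Extraction 9.5.3.1 (protocol GE1-v5_95_Feb07, array design 014868), per the file headers. The processed signal is an intensity that was background-subtracted and detrended within each array and not normalized between arrays, per the file headers. The mean spot and median background intensity were deposited without correction. The deposited value table holds log2 values, and its software is not stated. Set against the scanner values, it held log2 of the processed signal minus the array's 75th percentile, within 0.001 for 99.9% of probes. Its columns were not centred per probe, and their medians were -3.86, -3.87, -3.71 and -3.69 (four-factor cells at 21% and 5% O2, then untransduced fibroblasts at 21% and 5% O2).

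Each array had 45018 spots, of which 43379 were not controls, for 41174 probes. The value used was log2 of the processed signal minus the array's 75th percentile over probes. Spots marked as outliers by the extraction software (115, 119, 234 and 269 in the same order) were dropped and replicate spots averaged, with a standard deviation between replicate spots of 0.051, 0.055, 0.044 and 0.041 log2 units. This is the precision of a spot and not of a condition, which had 1 array. A gene was represented by its brightest probe over the arrays. Gene names came from the array files, and probe accessions were matched to a gene table of assembly GRCm38.p6 for names only, with 24375 probes matched. This gave 27739 gene names, 18827 of them in that table. Positions are those of build mm8 (NCBI 36), per the file headers. Of genes with several probes on both arrays, probes differed in direction for 30.0%, 26.9%, 24.7% and 23.6% (oxygen in four-factor cells, oxygen in untransduced fibroblasts, transduction at 21% and at 5% O2), but among genes at least 2-fold apart for 4 of 73, 2 of 112, 77 of 1252 and 113 of 1766.

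The 4 comparisons were 5% minus 21% O2 in each culture and four-factor minus untransduced at each oxygen level. With 1 array per condition these have no test. A gene was counted when it was at least 2-fold higher or lower and well above background on both arrays. For a gene measured on 1 array only, the fold is a lower bound, taken against the higher of the dim probe's own signal and the lowest signal well above background on that array (9.86, 9.66, 26.2 and 24.9 in intensity units). A simulation with 200 changed genes of 15252 and an assumed noise of 0.1 log2 units checked the counting only, and false calls between single cultures were not estimated.

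An additive limma model (lmFit and eBayes, Benjamini-Hochberg adjustment, adjusted p under 0.05) with terms for culture and oxygen was fitted to the 4 arrays over 18359 genes well above background on at least 2 arrays. It leaves 1 residual degree of freedom, so its error is the difference between the oxygen effects of both cultures, moderated over genes. In its simulation 200 genes were changed, each by the same amount in both cultures, and 1 unchanged gene was called.

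Before the data were examined, 20 gene lists were fixed. They covered hypoxia, glycolysis, the respiratory chain, NRF2 and antioxidant genes, pluripotency, fibroblast and mesenchyme, epithelium, and contractile and TGF-beta response. They also covered cell cycle, p53 targets and cell cycle inhibitors (as 1 list), ribosome biogenesis and MYC-bound genes, interferon, unfolded protein stress and cholesterol synthesis. The rest were markers of macrophages, endothelium, skeletal muscle, adipocytes, cartilage and bone, and neural cells. No gene is in more than 1 of these lists. A list's median covers members well above background on at least 1 of the 2 arrays, and is also given with dim members at their bounds where that moves it. A list stands apart when its median lies in the outermost 5% of 10000 random lists of the same size matched on mean expression in 20 bins. The designs, lists and most alternatives were fixed at the same time.

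Genes were named by a rule fixed then too: the 4 transduced genes; the 10 largest differences per direction in each oxygen comparison among genes whose probes agree, with up to 3 per direction by bound; the 10 per direction shared by both oxygen comparisons and by both four-factor comparisons; up to 4 members per list and comparison; 11 fixed genes; and the 5 largest differences that opposed each other with oxygen. Clone names, predicted genes and accessions were not named, and some genes that the rule covers are not reported here. Ocln, Ak4, Cldn4, Myod1, Rab25, Crb3, C1qa and Cdkn2c complete small counts or groups and were named after their values were seen. So were Pf4, Trem2, Ctss, Ms4a7, Xist, Ddx3y, Eif2s3y, Kdm5d, Hoxa10, Hoxc8, Hoxd8, Tbx4 and Tbx5 in the closing part.

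The alternatives were quantile normalization, scaling on the median of probes above background on all arrays, normexp background correction with an offset of 50, the deposited value table, the mean over a gene's probes, outlier marks ignored, other filters on dim probes, thresholds of 1.5-fold and 3-fold, eBayes with trend and robust, and an adjusted p under 0.1. Scaling on 7 spike-in controls was added after the data were seen. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.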

Results

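The data are 4 one-colour (Cy3) Agilent microarrays of total RNA from mouse embryonic fibroblasts, connective tissue cells grown from embryos. For 2 arrays the fibroblasts had been transduced with Oct3/4 (the gene Pou5f1), Sox2, Klf4 and c-Myc (the gene Myc), the transcription factors used to reprogramme fibroblasts towards pluripotency, and grown for 72 hours at 21% or 5% O2. These are called four-factor cells below, and their labels give day 4. For the other 2 arrays untransduced fibroblasts were grown for 10 days at 21% or 5% O2. Each condition had 1 array, so no difference between 2 arrays has a replicate check or a p-value, and the number of arrays limits the precision of every value. Of the 41174 probes, 68.1% and 68.4% were well above background in four-factor cells at 21% and 5% O2, and 57.1% and 58.3% in untransduced fibroblasts at 21% and 5% O2. The 75th percentile of signal was 1136 and 1150 on the four-factor arrays and 810 and 870 on the untransduced arrays, and no spot was saturated. The arrays of each culture lay on 1 slide of their own, so each oxygen comparison was made within a slide, while transduction, time in culture, slide and scan cannot be told apart in the four-factor comparisons. All differences are in log2 units of signal relative to the array's 75th percentile.

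The transduced genes were looked at first. Pou5f1 was well above background only in four-factor cells, at -0.59 (21% O2) and -0.20 (5% O2), and at least 20.6-fold and 30.5-fold higher there than in untransduced fibroblasts at the same oxygen level. Its probe lies on chromosome 17 from 35118388 to 35118448 (mouse build mm8, as for all positions here). Myc was higher in four-factor cells by 2.59 at 21% O2 and 4.17 at 5% O2 on its brightest probe (chromosome 15, 61819528 to 61819587). A second Myc probe (61819036 to 61819095) went the same way, from -1.52 in untransduced to 2.01 in four-factor cells at 21% O2. The remaining Myc probe (61819627 to 61819687) went the other way, from 2.03 to 0.52. Klf4 (chromosome 4, 55549061 to 55549120) was lower in four-factor cells, by -1.14 at 21% and -1.70 at 5% O2. Sox2 (chromosome 3, 34843400 to 34843459) was not well above background in four-factor cells at 21% O2, at least 5.14-fold below the untransduced fibroblasts, and the difference at 5% O2 was -2.82. Which part of each gene the vectors carried is not given in the sources used here, and a probe outside that part does not measure the transduced copy. Whether the Klf4, Sox2 and remaining Myc probes lie outside it is open. Their lower values do not bear out the labels, and whether they count against them cannot be decided here.

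The first comparison asked which genes differ with oxygen in reprogramming fibroblasts. In four-factor cells, hypoxia-response and glycolysis genes were higher at 5% than at 21% O2, led by Slc16a3, which exports lactate, at 4.64. Mgarp, a mitochondrial protein that is in neither of these lists, was higher by 4.45. Cell cycle genes and epithelial genes were higher as well, while contractile, fibroblast and NRF2 genes were lower. A few pluripotency genes that were dim at 21% O2 were higher at 5% O2, among them Tdgf1, a Nodal co-receptor, by at least 6.64-fold. Of 17999 genes well above background on both arrays, 225 were at least 2-fold higher and 194 at least 2-fold lower at 5% O2. A further 84 and 69 passed 2-fold by a lower bound because 1 array did not measure them. Scaling on the spike-in controls, added after the data were seen, gave 311 higher and 122 lower.

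The hypoxia response list, targets of the hypoxia-inducible factors, had a median difference of 0.66 in four-factor cells, and 23 of its 28 measured members were higher, 12 of them at least 2-fold. Bnip3, which acts in mitophagy, was higher by 3.09, Egln3, a prolyl hydroxylase that marks those factors for breakdown, by 3.06, Ankrd37 by 2.75 and Higd1a by 1.70. Vegfa, the angiogenic growth factor, was higher by 1.36. The median of the glycolysis and glucose uptake list was 0.74, with 20 of 21 members higher and 8 at least 2-fold. After Slc16a3 came the aldolase Aldoc at 2.71, Pdk1, the kinase that shuts pyruvate out of mitochondrial oxidation, at 2.64, and the glucose transporter Slc2a1 at 2.36. Pgk1 and Ldha, enzymes of the pathway itself, were higher by 1.0 and 0.74. The mitochondrial respiratory chain list did not move with them, with a median of 0.03 over 26 members and none past 2-fold. Both the hypoxia and the glycolysis list stood apart, that is, their medians lay in the outermost 5% of 10000 random lists matched on expression, which describes these arrays and is no test of the conditions.

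All 26 cell cycle genes were higher at 5% O2 in four-factor cells, with a median of 0.49 and none past 2-fold. Aurkb, a mitotic kinase, was higher by 0.81, Cdc6, which licenses replication origins, by 0.75, and Bub1, of the spindle checkpoint, by 0.71. The ribosome biogenesis list was higher by a median of 0.11, with 19 of 21 members higher, Rrs1 (0.36) the most. In the list of p53 targets and cell cycle inhibitors (median -0.20) the inhibitors Cdkn2b and Cdkn1a were lower, at -0.71 and -0.61. Its inhibitors Cdkn1c (0.35), Cdkn2a (0.30) and Cdkn2c (0.23) were higher, so the inhibitors went both ways. The epithelium list had a median of 0.57, or 0.30 with dim members set at their bounds, and 4 of 15 members were at least 2-fold higher, namely Krt8 (1.37), Cldn3 (1.33), Epcam (1.24) and Ocln. Krt8 is a keratin of simple epithelia and the other 3 are proteins of cell junctions or adhesion. In the fibroblast and mesenchyme list 24 of 25 members were lower, with a median of -0.26, Dcn (decorin) at -0.92 and the receptor Pdgfrb at -0.67 the furthest. The contractile list was lower by a median of -0.71, with 13 of 14 members lower and none past 2-fold, including Lmod1 (-0.91), the tropomyosin Tpm2 (-0.82), the smooth muscle actin Acta2 (-0.77) and the calponin Cnn1 (-0.75). These lists all stood apart.

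Of 17 pluripotency genes measured in four-factor cells, 6 were at least 2-fold higher at 5% O2 and none lower, but the list's median of 0.13 did not stand apart. Nr0b1 was higher by 2.09, Gdf3 by 1.55 and Zfp42 by 1.20. Nanog and Sox2 were measured at 5% O2 only and were at least 2.42-fold and 2.26-fold higher. The NRF2 and antioxidant list was lower by a median of -0.24, with 17 of 18 members lower, the quinone reductase Nqo1 at -1.15, Gsta3 at -0.96 and the haem oxygenase Hmox1 at -0.86. The interferon list had a median of -0.34 that stood apart, with members on both sides, from Rsad2 at 1.80 to the chemokine Cxcl10 at -1.28. With the normexp background correction its median was -0.00 and no longer stood apart. The unfolded protein list (-0.10), cholesterol synthesis (-0.04) and the markers of macrophages (-0.10), endothelium (-0.24), skeletal muscle (-0.14), adipocytes (0.03), cartilage and bone (-0.16) and neural cells (0.17) did not stand apart. Among their members Cldn5, a claudin of endothelial junctions, was higher by 2.68, the phosphatase Alpl by 1.17, Myh8 by 1.02 and Mbp by 1.02.

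By size alone, Slc16a3, Mgarp, Ppp1r3g (4.08), Smtnl2 (3.80), Bnip3, Egln3, Ankrd37, Aldoc, Cldn5 and Pdk1 were the 10 genes furthest up in four-factor cells. Rnd1, a small GTPase that loosens the actin cytoskeleton, was furthest down at -2.68, followed by the glutamate transporter Slc1a2 (-2.30), Jaml (-2.12), Tmem45a2 (-2.06), Prl3d2 (-2.04), Lce1h (-2.01), Tg (-1.98), Uts2b (-1.94), Wnt7a (-1.86) and Lce1i (-1.79). By bound, Gpr63 was at least 5.87-fold and Psg29 at least 5.6-fold higher, and Igl-V1, Tff3 and Mucl2 were at least 8.34-fold, 4.69-fold and 3.83-fold lower. Many of the genes lower in this comparison were dim. With the normexp background correction the counts were 97 and 39, and 25 of the values named for this comparison were under 2-fold, among them Slc1a2, Jaml, Tmem45a2, Prl3d2, Tg, Uts2b, Wnt7a, Epcam, Gdf3, Zfp42, Rsad2, Cxcl10, Myh8 and Mbp.

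The second comparison asked the same of untransduced fibroblasts. Here too hypoxia genes were higher at 5% O2 and contractile genes lower. The largest median of any list, however, was that of the macrophage markers, of which all 14 measured were higher at 5% O2 and 13 at least 2-fold. F13a1, a coagulation factor subunit that macrophages also make, led the genes that were higher, at 3.78, and Ptgs2, the inducible cyclooxygenase, led those that were lower, at -3.09. Of 15252 genes measured on both arrays, 389 were at least 2-fold higher and 263 at least 2-fold lower, with 155 and 150 more by bound. With spike-in scaling 325 were higher and 319 lower.

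The hypoxia list had a median of 0.57 in untransduced fibroblasts, with 21 of 27 members higher. At least 2-fold higher were Ankrd37 (2.52), Egln3 (1.84), the lipase inhibitor Angptl4 (1.64), Bnip3 (1.23) and Ak4. Vegfa was higher by 0.57. In the glycolysis list (median 0.28) 18 of 21 members were higher, and Slc16a3 (2.22), Aldoc (1.42) and Pdk1 (1.38) passed 2-fold, while Slc2a1 (0.60), Pgk1 (0.40) and Ldha (0.28) did not. The contractile list had a median of -1.07, with 8 of 14 members at least 2-fold lower, including Cnn1 (-1.90), Lmod1 (-1.72), the smooth muscle actin Actg2 (-1.60) and Ccn2 (-1.51), a matricellular protein induced by TGF-beta. Ankrd1 (-2.39) and Fosl1 (-2.31), neither of them in a list, were also among the 10 genes furthest down. The cardiac and skeletal actins Actc1 (-1.82) and Acta1 (-1.74) were lower too, although the muscle list as a whole (median -0.15) did not stand apart.

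The macrophage list had a median of 1.39 (quartiles 1.17 to 1.57) in untransduced fibroblasts and stood apart. The mannose receptor Mrc1 was higher by 1.98, Adgre1 (F4/80) by 1.82, the complement component C1qc by 1.76 and the receptor Csf1r by 1.57. The adipocyte list was higher by a median of 0.82, or 0.43 with bounds, with the lipoprotein lipase Lpl at 1.17 and the fatty acid carrier Fabp4 at 1.12. The neural and glial list had a median of 0.21 that did not stand apart, with 5 members higher and 4 lower, and in it Sox10 was at 1.85, S100b at 1.21 and Mbp at 1.03. Markers of endothelium (-0.20) and of cartilage and bone (-0.18) had medians that did not stand apart, with Tek (1.72) and Emcn (-1.79), both endothelial, on opposite sides and Spp1 (-2.21) and Col10a1 (-1.44) lower. The fibroblast list did not stand apart either (-0.03), with Pdgfra at 0.82 and S100a4 at -0.81.

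Cell cycle, ribosome biogenesis and cholesterol synthesis genes were lower at 5% O2 in untransduced fibroblasts, with medians of less than 2-fold. Of 26 cell cycle genes 25 were lower (median -0.29), among them Cdc6 (-0.76), Rrm2 (-0.67) and Mcm5 (-0.51), and of 21 ribosome biogenesis genes 20 were lower (-0.30). All 18 cholesterol synthesis genes were lower (-0.57), including the sterol carrier Stard4 (-0.76) and the sterol sensor Insig1 (-0.75). The list of p53 targets and cell cycle inhibitors was lower (-0.46), with the apoptosis gene Pmaip1 at -1.66 and Cdkn1a at -0.60. Its cell cycle inhibitor Cdkn1c was higher by 1.5. The NRF2 list was lower (-0.23, Nqo1 at -0.76). The interferon list was higher (0.30), with Oasl2 at 1.26 and Ifit1 at 0.76 but Ccl5 at -1.12. Epithelium had a median of 0.78, with Krt8 at 0.88, Cdh1 at least 2.24-fold higher, Cldn4 past 2-fold and Perp at -1.01, but the sign turned to -0.18 with no filter on dim probes. The respiratory chain (-0.19), the unfolded protein list (-0.08) and the pluripotency list (0.15, with Sox2 at 1.63 and Gdf3 lower) did not stand apart.

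The 10 genes furthest up in untransduced fibroblasts were F13a1, the prostaglandin D synthase Ptgds (3.58), Gpr17 (2.90), vitronectin (Vtn, 2.86), Mgarp (2.82), Lrrc23 (2.74), Zfp114 (2.69), Wdr86 (2.67), Tnxb (2.55) and Myoc (2.55). Among those furthest down, besides Ptgs2, Ankrd1, Fosl1 and Spp1, were Crct1 (-2.71), the chemokines Ccl2 (-2.37) and Ccl20 (-2.37), Cck (-2.27) and Amdhd1 (-2.16). By bound, Cldn11 was at least 12.1-fold, Slco2b1 at least 7.22-fold and Arg1 at least 6.40-fold higher, and Slc26a8, Lce1i and Omg were at least 8.17-fold, 8.08-fold and 6.52-fold lower. With normexp the counts were 197 and 132.

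**Figure D1:**
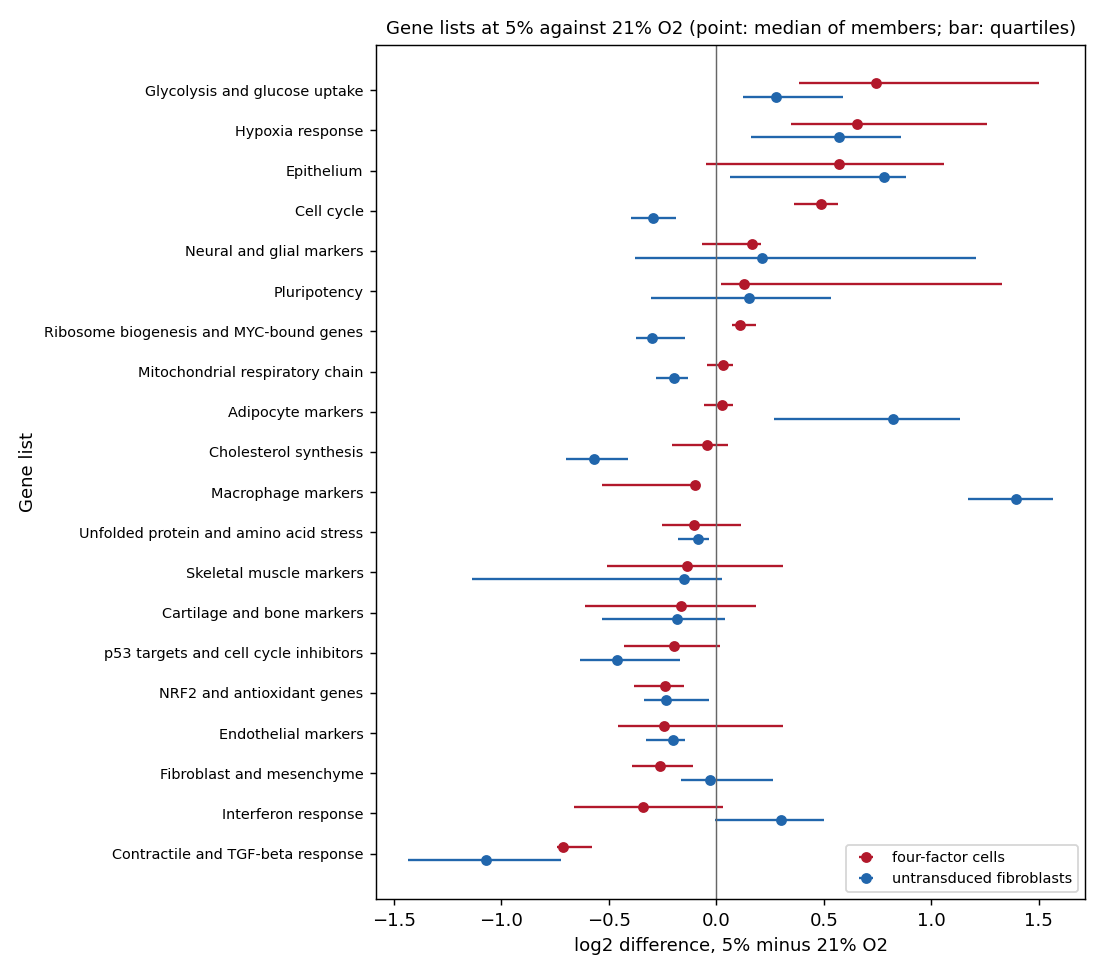
Median log2 difference between 5% and 21% O2 (x axis) of each gene list (y axis) in four-factor cells and in untransduced fibroblasts, 1 array per condition; points are medians and bars the quartiles over list members. Hypoxia and glycolysis lie to the right of 0 and contractile genes to the left in both cultures, while the cell cycle list lies at 0.49 in four-factor cells and -0.29 in untransduced fibroblasts and macrophage markers reach 1.39 in untransduced fibroblasts only.

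Set side by side, the oxygen differences of both cultures, which share no array, had a part in common. Over 14982 genes measured on all arrays they correlated weakly (Pearson r 0.25, Spearman rho 0.17, across genes, which are not independent replicates). At least 2-fold higher in both were 33 genes, against 2.53 for independent lists of these sizes, and 30 were lower in both, against 1.98. Besides Mgarp, Ankrd37, Slc16a3, Egln3, Aldoc and Pdk1, the shared genes with the largest smaller difference were the glycogen phosphorylase Pygl (2.31 in four-factor cells and 1.74 in untransduced fibroblasts), Selenbp1 (1.86 and 1.51), Selenbp2 (1.85 and 1.45) and the peptidase Dpp4 (1.44 and 1.78). Lower in both were Rnd1 (-2.68 and -1.65), Ifi27l2b (-1.49 and -1.95), Serpinb10 (-1.45 and -1.62), Tnfsf18 (-1.44 and -1.54), Tg (-1.98 and -1.35), Ces2e (-1.25 and -1.33), Ankrd1 (-1.22 and -2.39), Lrrc4c (-1.21 and -1.99), Crct1 (-1.17 and -2.71) and the growth factor Fgf5 (-1.20 and -1.15). Of these 10, Ankrd1, Crct1 and Rnd1 stayed past 2-fold in both cultures with normexp.

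A limma model with terms for culture and oxygen over the 4 arrays tested for an oxygen difference common to both cultures, with the difference between the cultures as its error. No gene of 18359 passed at an adjusted p of 0.05 (smallest 0.436), while 647 genes higher and 754 lower had an unadjusted p under 0.05. With normexp 74 genes higher and 95 lower passed. Adjusted over the list alone, 14 of 28 hypoxia genes were higher and 1 lower, against 0 over all genes. The 14 became 1 when genes above background on any array were fitted. Ankrd37 had an estimate of 2.63 (SE 0.17, adjusted p over the list 0.00393, limma), Egln3 2.45 (SE 0.35), Bnip3 2.16 (SE 0.50), Angptl4 1.33 (SE 0.23) and Vegfa 0.96 (SE 0.26). In the contractile list 11 of 14 genes were lower over the list alone, among them Cnn1 at -1.32 (SE 0.34), Lmod1 at -1.31 (SE 0.26), Ccn2 at -1.11 (SE 0.26) and Acta2 at -0.98 (SE 0.19), with adjusted p between 0.0216 and 0.0257 over the list. Glycolysis had 3 higher (Slc16a3, Aldoc and Pdk1, a count that ran from 0 to 11 over the alternatives), epithelium 2 (Krt8 and Cldn7), and pluripotency (Sox2), neural (Mbp) and macrophage markers (C1qa) 1 each. C1qa was dim on both four-factor arrays and Sox2 on 1 of them, so these 2 calls rest partly on signals near background. The other 13 lists had none. In simulated data of these 18359 genes, each changed gene had the same oxygen effect in both cultures. The oxygen term recovered 0% of genes changed by 1 log2 unit, 24% at 2, 94% at 3 and 94% at 4. A count of 0 thus leaves room for common changes. Effects of unequal size in the cultures add to the error, and their recovery was not simulated. Large estimates in the data, such as Mgarp (3.63, SE 0.45) and Slc16a3 (3.43, SE 0.64), were not among the calls over all genes. The oxygen difference of Slc16a3 was 4.64 in four-factor cells and 2.22 in untransduced fibroblasts. In the model that difference is the error behind the SE of 0.64, and the adjusted p of Slc16a3 over all genes was 0.594 (limma). Other reasons were not tested.

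**Figure D2:**
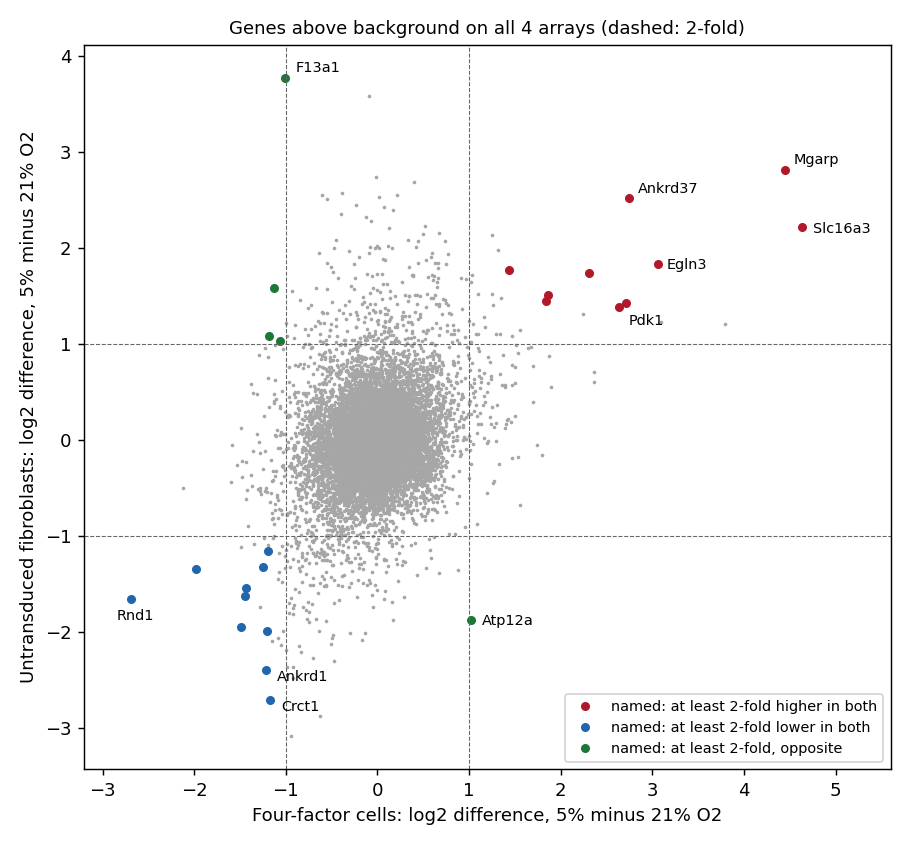
Log2 difference between 5% and 21% O2 in four-factor cells (x axis) and in untransduced fibroblasts (y axis) for genes well above background on all 4 arrays; each point is a gene, dashed lines mark 2-fold, and coloured points are the named genes. Mgarp, Slc16a3, Ankrd37 and Egln3 stand at the upper right, Rnd1, Ankrd1 and Crct1 at the lower left, and F13a1 at -1.01 and 3.78.

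The last 2 comparisons set four-factor cells against untransduced fibroblasts at the same oxygen level and asked how far the transduced cells had left the fibroblast state. At both oxygen levels the four-factor cells had lower fibroblast, interferon and macrophage genes and higher cell cycle, ribosome biogenesis and epithelial genes. At 21% O2, 1808 genes were at least 2-fold higher and 2536 lower of 15272 measured, and at 5% O2 2649 were higher and 3098 lower of 15504, with 365 and 393 more by bound at 21% and 408 and 467 at 5% O2. The comparisons share no array, and their differences correlated over 14982 genes (Pearson r 0.94, Spearman rho 0.93, across genes), with 1594 genes higher in both (302 for independent lists) and 2124 lower in both (464). By the culture term of the limma model, which also holds time in culture, slide and scan, 4997 genes rose and 4173 fell of 18359 (smallest adjusted p 0.00298). Of these, 1302 and 234 were dim on both arrays of a culture, where the model used signals near background, and 544 and 49 had a bound of 0 at both oxygen levels. Scaling on the spike-in controls, added after the data were seen, moved the split to 3667 higher and 1610 lower at 21% O2 and 5625 and 1675 at 5% O2.

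In the limma model 19 of 20 interferon response genes fell in four-factor cells. Its median was -2.70 at 21% and -2.84 at 5% O2, with Ifit1 at -4.48 and -5.77 (-5.13 in the model, SE 0.37, adjusted p 0.00445), Ifit3 at -4.33 and -5.38, Oasl2 at -3.60 and -5.20 and Mx2 at -3.62 and -4.54. Macrophage markers fell in 11 of 15 members and rose in 1, Itgam, which was dim in untransduced fibroblasts. Their medians were -2.96 and -4.86 (-4.48 with bounds), with Lyz2, the macrophage lysozyme, at -6.07 and -7.26 and Csf1r at -2.36 and -4.48. Laptm5, measured on all arrays and not called as risen, was at 1.74 and 0.34, and Cd68 was at 0.85 and -1.04. The fibroblast list fell in 20 of 25 members and rose in none, with medians of -1.07 and -1.56. Lumican (Lum) was at -5.60 and -6.31 (-5.95 in the model, SE 0.24, adjusted p 0.00298), periostin (Postn) at -3.94 and -4.20, Pdgfra at -3.28 and -4.30, Dcn at -3.26 and -4.75 and the surface antigen Thy1 at -1.78 and -1.78. Contractile and TGF-beta response genes fell in 8 of 14, with medians of -0.94 and -0.60, the latter 0.056 with spike-in scaling. The integrin Itga11 (-3.63 and -3.30), Thbs1 (-1.5 and -1.25) and Lmod1 (-1.98 and -1.18) were the furthest. At 5% O2 3 of the 14 were higher, namely Actg2 (0.62), Cnn1 (0.47) and Smad7 (0.43). The unfolded protein and amino acid stress list fell in 9 of 16 and rose in 2 (medians -0.77 and -0.79), with Trib3 at -3.19 and -3.54, Chac1 at -2.74 and -2.57 and Ddit3 at -2.09 and -2.95.

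Cell cycle genes rose in 24 of 26, with medians of 1.40 at 21% and 2.11 at 5% O2, including Cdc6 at 2.35 and 3.86 (3.11 in the model, SE 0.42, adjusted p 0.0110), Mcm5, of the replicative helicase, at 2.26 and 3.20, and the mitotic kinase Plk1 at 1.74 and 2.18. Ribosome biogenesis and MYC-bound genes rose in 20 of 21 (medians 1.45 and 1.74), with Dkc1 at 2.95 and 2.77, Cad, which starts pyrimidine synthesis, at 2.06 and 2.18 and Nolc1 at 2.02 and 2.5. The epithelium list rose in 10 of 13 and fell in 2, with medians of 2.32 and 2.22, or 0.28 and 0.46 with bounds. Of the 10, 4 were dim on both untransduced arrays, and 2 of these had a bound of 0, Crb3 at 21% O2 and Rab25 at both oxygen levels. Krt8 was at 4.12 and 4.60 (4.36 in the model, SE 0.20, adjusted p 0.00311), the desmosomal Dsp at 3.98 and 4.97, Cldn3 at 5.62 at 5% O2, and the E-cadherin gene Cdh1 at least 7.29-fold higher at 21% and 2.28 at 5% O2, while Krt7 was at -2.54 and -3.53. In the pluripotency list, Tdh, a threonine dehydrogenase of mouse pluripotent cells, was at 4.88 and 5.43, and Fbxo15 was at least 4.72-fold higher at 21% and 2.18 at 5% O2. Dppa5a was at -1.78 and -2.25 and Nanog was above background at 5% O2 only, without a fold against untransduced fibroblasts. The list's median was 0.44 (0.15 with bounds) at 21% O2 and stood apart only at 5% O2 (1.25, 0.47 with bounds), and 6 of 15 members rose and 2 fell. Of the 6, 1 is the transduced Pou5f1, and 4, Pou5f1 included, were dim on both untransduced arrays, of which Zfp42 had a bound of 0 at 21% O2.

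Glycolysis genes stood apart at 5% O2 (median 1.17, 15 of 21 at least 2-fold higher) and not at 21% O2 (0.47, 3 of 21), and 10 rose and 1 fell in the model. The hexokinase Hk2 was at 1.62 and 2.73, Pfkp at 1.88 and 2.58 and the glucose transporter Slc2a3 at 1.54 and 2.28, though Slc2a3 was at -0.33 at 21% O2 as a mean over its probes. The hypoxia list went both ways, with 12 genes that rose and 8 that fell of 28, medians of 0.33 and 0.71 (the latter standing apart), Egln3 at 3.01 and 4.24 and Ankrd37 at 2.55 and 2.78, but Lox at -2.39 and -2.86 and Adm at -2.36 and -1.88. Respiratory chain genes rose in 13 of 26 and fell in none, with medians of 0.49 and 0.63 that did not stand apart, Cyc1 at 0.84 and 1.26. NRF2 genes rose in 8 and fell in 4 of 18 (medians 0.57, which stood apart, and 0.41), with Gsta4 at 1.86 and 1.71 and Gpx3 at -2.76 and -3.62. Of 20 p53 targets and cell cycle inhibitors 4 rose and 6 fell (medians -0.07 and 0.10), the inhibitor Cdkn1c at -3.95 and -5.11 the furthest. Of 18 cholesterol genes 2 rose (0.00 and 0.42), with Idi1 at 1.21 and 1.76. Cdkn2a, an inhibitor that limits reprogramming, was at -0.97 and -0.01, Gapdh at 0.85 and 1.02 and Actb at -0.70 and -0.55, on a probe that the files place on the X chromosome, so whether it measures Actb is open.

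Among markers of other cell types, adipocyte genes stood apart at 5% O2 (median -1.90, or -1.87 with bounds, and -0.58 at 21% O2), with 2 that rose and 3 that fell of 6 and Lpl at -4.80 and -5.89. Cartilage and bone markers rose in 2 and fell in 6 of 12 (medians -0.22, or -0.27 with bounds, and -0.36), Comp at -5.11 and -5.67 and Sox9 at -2.96 and -3.10. Neural and glial markers rose in 4 and fell in 4 of 10 (medians -0.30 and -0.12, or -0.29 and -0.61 with bounds), with the neuronal genes Stmn2 at 2.54 and 3.09 and Tubb3 at 2.25 and 2.20 and the glial Sox10 at -2.83 and -5.22. Endothelial markers rose in 2 and fell in 2 of 9 (medians 0.87 and -0.52, both 0 with bounds), Erg at -4.19 and -4.06 and Tek at 2.61 and 1.27. Skeletal muscle markers fell in 2 of 9 (medians 0.08 and 0.20, the former 0 with bounds), Tnnc2 at -1.19 and -1.33, and the 1 that rose, Myod1, was dim on both untransduced arrays, with a bound of 0 at both oxygen levels. Except for adipocytes at 5% O2, none of these lists stood apart, and medians of lists that did not stand apart differed in sign between scalings. Adjusted over the list alone, the counts of genes that rose and fell were 9 and 4 for NRF2, 2 and 22 for fibroblast, 0 and 9 for contractile, 21 and 0 for ribosome biogenesis, 3 and 10 for unfolded protein, 1 and 0 for cholesterol, 1 and 12 for macrophage and 4 and 5 for neural genes, and as over all genes for the other 12 lists.

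By the smaller of both differences, the genes furthest up were Nat8l (7.92 and 7.28, 7.60 in the model, SE 0.23, adjusted p 0.00298), the chloride channel Ano1 (6.73 and 7.68), the thyroid hormone binding Crym (7.70 and 6.58), Plekhh1 (6.20 and 7.21), Sostdc1 (6.53 and 6.19), Urah (5.64 and 5.61), Ccdc88c (5.50 and 5.65), the neurofilament gene Nefl (5.35 and 5.42), Gna14 (5.27 and 5.05) and Tdh. Furthest down were the collagen Col8a2 (-9.08 and -9.37, -9.22 in the model, SE 0.18, adjusted p 0.00298), the angiotensin receptor Agtr2 (-7.19 and -8.06), Angptl1 (-6.87 and -8.07), the interferon-induced GTPase Iigp1 (-6.65 and -8.06), Mfap4 (-6.62 and -7.73), Kcnj8 (-6.61 and -7.71), Thbs4 (-6.91 and -6.45), Mup4 (-6.38 and -6.90), Epyc (-6.28 and -6.86) and Olfml1 (-6.27 and -6.82). By bound, Ceacam2 was at least 249-fold and 335-fold, Scg5 at least 172-fold and 237-fold and Anxa10 at least 459-fold and 157-fold higher, and Mup1, Meox1 and Gpr17 were at least 106-fold, 82.0-fold and 77.3-fold lower at 21% O2 and 165-fold, 145.9-fold and 597-fold lower at 5% O2.

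**Figure D3:**
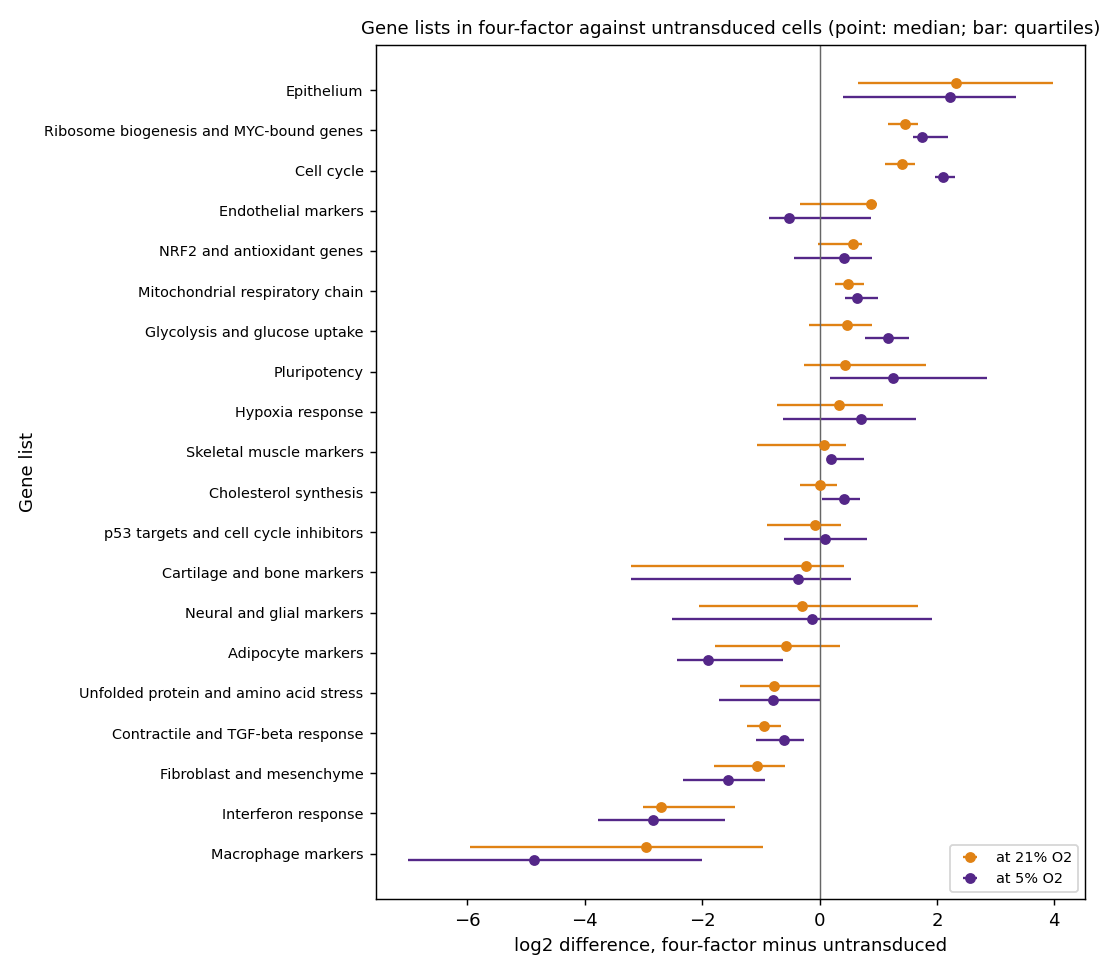
Median log2 difference between four-factor cells and untransduced fibroblasts (x axis) of each gene list (y axis) at 21% and at 5% O2, 1 array per condition; points are medians and bars the quartiles over list members. Epithelium, ribosome biogenesis and cell cycle lie to the right and fibroblast, interferon and macrophage genes to the left at both oxygen levels, while the contractile list at 5% O2 (-0.60) is at 0.056 with spike-in scaling.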

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

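The tests of compressed signals, of intensity, of time in culture, of a lower share of fibroblasts and of scaling on the macrophage markers were chosen after the result was seen, and the others before. With 1 array per condition, none of the differences between cultures given here was tested.

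These results went in opposite directions with oxygen in the 2 cultures. The cell cycle list had a median of 0.49 at 5% against 21% O2 in four-factor cells and -0.29 in untransduced fibroblasts. The ribosome biogenesis list had medians of 0.11 and -0.30. The interferon list had medians of -0.34 and 0.30, but with normexp the four-factor median was -0.00 and no longer stood apart. Adamdec1, a protease of macrophages and dendritic cells, was at -1.13 and 1.58, the homeobox gene Dbx2 at -1.19 and 1.09, Rapgef5 at -1.06 and 1.04, the proton pump Atp12a at 1.02 and -1.87 and F13a1 at -1.01 and 3.78. With normexp all 5 of these genes were under 2-fold in four-factor cells.

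Macrophage markers were higher at 5% O2 in untransduced fibroblasts, with a list median of 1.39. A larger share of macrophages in that culture predicts the same for other macrophage genes, and a second list of 28 genes that shares none with the first had a median of 1.33 (1.29 with dim members at their bounds), with 21 of 23 measured members higher. Lyz2 went from 3.85 to 4.94, Ctss from -1.34 to 0.08, and the labels name no sort that would remove such cells. A lower share of fibroblasts alone would raise the markers of other cell types alike. In 4 of the 5 other lists of cell type markers the upper quartile lay below the macrophage list's lower quartile of 1.17. It was -0.14 for endothelium, 0.03 for skeletal muscle and 0.04 for cartilage and bone, but 1.14 for adipocytes. For neural and glial markers it was 1.21. Not all other markers thus rose alike, but a rise shared with adipocyte or neural and glial markers is left open. The lowest macrophage median over 4 other scalings and background corrections was 1.09. A larger share of macrophages, or macrophage genes switched on more in the same cells, may account for the higher macrophage markers, and the arrays do not separate these.

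The four-factor cells at 5% O2 lay further along the four-factor difference than those at 21% O2. Over 14934 genes outside the hypoxia and glycolysis lists, the slope of their oxygen difference on the mean four-factor difference was 0.0813 and positive in 10 of 10 expression bins, and 140 genes dark in untransduced fibroblasts, picked as measured on both four-factor arrays and at least 4-fold apart by bound, were higher at 5% O2 by a median of 0.26, with 91 higher and 49 lower. An oxygen effect common to both cultures predicts the same sign in untransduced fibroblasts, where the slope was -0.103. Macrophage and cell cycle genes measured on all arrays were kept there. In untransduced fibroblasts their list medians with oxygen were 1.39 and -0.29, opposite in sign to their four-factor differences (-2.96 and 1.40 at 21% O2). A common part hidden under such changes is therefore not excluded by the sign. A difference between the arrays that depends on intensity predicts no slope among genes of equal signal on them, where it was 0.0894 and positive in 20 of 20 bins. With normexp the slope in four-factor cells was 0.0617 and positive in 9 of 10 bins. A transduced programme that is further along, or present in more of the cells, is a candidate explanation, and these cannot be told apart on whole cultures with 1 array each. The four-factor difference also holds time in culture, slide and scan. Cell cycle genes, all 26 higher at 5% O2 in four-factor cells, were kept in the slope. Their medians along the four-factor difference were 1.40 at 21% and 2.11 at 5% O2. The slope therefore does not separate the programme from these.

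The hypoxia and glycolysis lists differed more with oxygen in four-factor cells. Compressed signals on the untransduced slide would show in the spike-in controls, but the ratio of their slopes (untransduced over four-factor) was 0.978 while that of the glycolysis medians was 0.375, with 19 of 21 members larger in four-factor cells. For the hypoxia list the ratio of medians was 0.872, with 20 of 27 members larger in four-factor cells. After the four-factor values were compressed by the ratio of the controls, they still exceeded the untransduced ones by a median of 0.354 (quartiles -0.00 to 0.59), above 99.98% of 10000 matched random lists. Compression of the size seen in the controls is thus not the whole cause for either list, and the lists were treated apart only after the result was seen. Time in culture rather than transduction stays open as a cause, since there were 0 untransduced arrays at 72 hours.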

How the results depend on the processing

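The spike-in scaling was chosen after the results were seen, and the other alternatives before. Arrays are paired by culture only in the limma model, through its culture term, and a fit of it without 1 array has no residual degree of freedom. Slide and scan as a block were not run because they coincide with the culture, and for list medians the filter on at least 1 of the 2 arrays is already in use.

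Counts are given as higher and lower, for oxygen in four-factor cells, oxygen in untransduced fibroblasts, transduction at 21% O2 and transduction at 5% O2, where they moved by over 1.5 times. With normexp the oxygen counts were 97 and 39, and 197 and 132, and the oxygen term of the limma model had 74 and 95 in place of 0. The moderation over genes in that model had 12.0 prior degrees of freedom with normexp and 2.82 in the main setting. The cause of these changes was not tested. With genes above background on at least 1 array the counts were 450 and 393, 778 and 556, and 3050 and 4070 higher for transduction at 21% and 5% O2. With no filter they were 907 and 910, 1078 and 1111, 3050 and 9847, and 4070 and 10057, and 10756 genes were lower by the culture term. More genes were counted in these settings. The genes added by dropping the filter were dim on both arrays. For transduction they left the higher counts at 3050 and 4070 and raised the lower counts from 3022 and 3634. The lowest signal well above background was -6.85 and -6.90 log2 units on the four-factor arrays and -4.95 and -5.13 on the untransduced ones. The rise thus lies in dim genes, and background relative to the 75th percentile differed between the cultures. Its share in the rise was not tested. A threshold of 1.5-fold gave 860 and 1026, 1054 and 874, 3551 and 3979, and 4345 and 4673, and 3-fold gave 47 and 23, 113 and 57, 684 and 1356, and 1181 and 1780, by construction. Spike-in scaling gave 122 lower for oxygen in four-factor cells, 3667 and 1610 at 21% and 5625 and 1675 at 5% O2, since the controls' own median differences, which it sets to 0, were -0.13, 0.07, -0.44 and -0.66 in the 4 comparisons.

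The share of counted genes that were higher was 53.7%, 59.7%, 41.6% and 46.1%. In the first comparison it was 71.3% with normexp, 67.1% at 3-fold and 71.8% with spike-in scaling. With no filter it was 49.2% in the second, 23.6% in the third and 28.8% in the fourth, and spike-in scaling gave 69.5% in the third and 77.1% in the fourth. The other 86 counts stayed within 1.5 times. Of these, 12 came from the deposited value table and 12 with outlier marks ignored, which are nearly the main values.

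Changes of sign were counted as reversals for lists only where the list stood apart. Values that reversed were, first, Slc2a3 for transduction at 21% O2 (-0.33 as a mean over its probes). The contractile list for transduction at 5% O2 (0.056 with spike-in scaling, by the shift above) was next. The last was the epithelium list for oxygen in untransduced fibroblasts (-0.18 with no filter). For the first and last the cause was not tested. Of the other list medians, 619 were on the same side of the rule, 16 came to stand apart and 3 no longer did. Many of the 619 could hardly differ. The deposited value table (80 of them) and the values with outlier marks ignored (80) are nearly the main values. Scaling on the median (80) and on spike-in controls (79) shifts each array by a constant, which cannot move a list against matched random lists. Of the values of named genes 2703 were on the same side of 2-fold, 80 fell under it (44 with normexp, 27 with the mean over probes and 9 with quantile normalization) and 6 passed it. Of the 2703, 465 came from the deposited value table and 465 with outlier marks ignored, again nearly the main values. Among list members in the limma model, 11 or 12 contractile genes were lower with oxygen in each of the 11 settings. Between 13 and 19 hypoxia genes were higher, except 1 with genes above background on any array, and for glycolysis the count ran from 0 to 11. Precision by signal level was not measured.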

Other observations

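The body position and sex-linked genes were chosen after the main results were seen, and no test was run on them.

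Genes of body position, which keep the site a fibroblast came from, and genes linked to sex were looked at as marks of where each culture came from. Of 16 body position genes none measured on both arrays was 2-fold apart with oxygen in either culture. Tbx4, which was dim in untransduced fibroblasts at 21% O2, was at least 2.08-fold higher there at 5% O2. The medians of the 16 were -0.13 in four-factor cells and 0.01 in untransduced fibroblasts. Between four-factor and untransduced cells 3 were at least 2-fold lower at each oxygen level, namely Hoxa10 (-1.35), Hoxd8 (-1.09) and Tbx5 (-1.04) at 21% O2 and Hoxd8 (-1.5), Hoxc8 (-1.40) and Tbx5 (-1.29) at 5% O2. Xist, the RNA that silences an X chromosome in female cells, was on all arrays and lower in four-factor cells by -1.45 at 21% and -1.67 at 5% O2. The Y-linked genes Ddx3y (0.31 and 0.30), Eif2s3y (0.39 and 0.61) and Kdm5d (0.45 and 0.63) were on all arrays too and slightly higher in four-factor cells. With oxygen Xist was at -0.23 in four-factor cells and -0.01 in untransduced fibroblasts. RNA of Xist and of Y-linked genes was thus present in every culture, in proportions that were not measured.

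In the second macrophage list, Pf4 was higher by 2.01 at 5% O2 in untransduced fibroblasts, Ms4a7 by 1.57, Trem2 by 1.56 and Ctss by 1.42. In four-factor cells the list's median with oxygen was -0.25, in the outermost 5% of matched random lists, although 7 members were higher and 9 lower. Against untransduced fibroblasts it was -1.49 at 21% and -3.65 at 5% O2, the latter -2.45 with dim members at their bounds.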
